A study of Mus musculus with 2 samples.

How the data were processed

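The data were single-cell RNA-seq of germ cells from adult C57BL/6 mouse testis, with 1 library from a wild-type testis and 1 from a testis labelled Zfp541-/-. Zfp541 encodes a zinc finger protein of male germ cells. Per the labels' protocols, the tissue was digested with collagenase IV, hyaluronidase, trypsin and DNase I, tetraploid germ cells were collected by flow cytometry, and the cells were loaded on the 10x Chromium system with the version 3 kit for 3' ends. The sample titles call the same libraries whole testis, whereas the source field names tetraploid germ cells, and the sort is taken from the protocol. A 3' kit counts molecules near the end of each transcript.

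Per the submitters' processing notes, Cell Ranger 3.1.0 with the mm10 genome and Seurat 3.2.0 were used. The deposited matrix of each library holds whole-number counts of unique molecular identifiers (UMIs) per gene and cell barcode, with no normalisation. The matrices hold 31053 genes, and no barcode had fewer than 500 UMIs. The authors' cell table gives, per the file headers, the total UMI count of each annotated cell, the percent of its UMIs from mitochondrially encoded genes, a cluster number, a stage name and a pseudotime score. That deposited score is a whole-number order with no unit, and how the authors computed it is not given in the sources used here. The table covers 17253 cells in 25 clusters and 15 stages, the cell and stage numbers that the series text states. Every annotated cell had at least 1000 genes and at most 10% mitochondrial UMIs, which were read from the values as apparent filters. A merged matrix of the same cells was not used, because its entries were the same as those of the library matrices.

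Cells were grouped by library and by the authors' stage names: 3 stages of differentiated spermatogonia, preleptotene, leptotene (L), zygotene (Z), early (eP), mid (mP) and late pachytene (lP), diplotene (D), the first meiotic division (MI), 3 stages of round spermatids (RS) and elongated spermatids (ES). Cells of a library are not replicates, and with 1 library per genotype there was no test, no p-value and no count of genes that differ. Except where an interval over genes is named, every interval is a 95% interval for counting error only. It is exact Poisson for a sum of UMIs, exact Clopper-Pearson for a share, and the exact conditional binomial interval for a ratio of sums. It leaves out variation between mice and between library preparations. A count of 0 was read as allowing up to 3 counts in that library.

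UMIs were summed per gene, stage and library and scaled to counts per 1000000 UMIs (CPM). The log2 ratio of the library labelled Zfp541-/- to the wild-type library was taken after adding 0.5 counts to each sum, which pulls the ratios of low genes towards 0. Ratios were taken in stages with at least 50 cells in each library, which were eP, mP and lP, and for genes of at least 10 CPM in the higher library. The median log2 ratio over genes was 0.26 in eP, 0.15 in mP and 0.11 in lP. Scaling by the median of ratios would move every log2 ratio by -0.16 in eP, 0.03 in mP and 0.09 in lP.

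The stage names were checked against marker genes, by counting a stage's own and other stages' markers among the 10 genes with the highest fold in each cluster. The eP clusters, numbers 12 and 16, each had 1 spermatogonium marker, Sohlh2, and 0 pachytene markers there. The preleptotene cluster, number 18, had 0 markers of its own and 1 leptotene-zygotene marker. Early pachytene genes and lists are therefore compared within cluster 12 and within cluster 16, and mP and lP as named stages. Means over the 3 shared stages, the choice of genes for the heat map and the comparison of ratios between stages still use eP as annotated. So do summed list levels, sex chromosome shares, UMIs per cell and widths of the ratios in eP. The libraries mix clusters 12 and 16 differently in that stage. No other cluster had more markers of another stage than of its own. The mP and lP clusters also had 0 pachytene markers among these 10 genes. The check therefore neither bears out nor contradicts the mP and lP names.

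Gene lists were fixed before the data were examined. They were the ZFP541 complex, double-strand break formation and recombination, synaptonemal complex and meiotic cohesin, premeiotic S phase and meiotic entry, sex chromosome silencing factors, X-linked genes, Y-linked genes, the piRNA pathway, G2/M and meiotic division, transcription regulators of pachytene and spermatids, acrosome, flagellum and axoneme, testis energy metabolism, p53 targets and apoptosis, testis histones, immediate early and heat shock genes, ribosomal proteins and mitochondrially encoded genes. Marker lists covered spermatogonia, preleptotene, leptotene-zygotene, pachytene, diplotene and meiotic division, round spermatids, elongating spermatids, Sertoli, Leydig, peritubular myoid and endothelial cells, macrophages and red cells. A list needed at least 5 measured members. Its value is the median log2 ratio of its members, per stage and as the mean over the 3 shared stages. Its percentile among 10000 random gene lists of the same size, matched on mean expression in 20 bins, describes these 2 libraries and is not a test of genotype.

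Named genes followed a rule fixed before the data were examined. They were Zfp541 and the complex members, the 10 genes with the largest and the 10 with the smallest ratio per shared stage and over the stages, and 2 to 4 members of each list with the largest mean ratio. The ranking within a stage used the bound of the counting interval nearest to 0, among genes of at least 50 CPM in the higher library. Mitochondrially encoded, ribosomal protein and Y-linked genes were left out of the ranking. Genes chosen after their values were seen are named as such. Of the genes that the rule names, 1 is not reported here. Positions are from the GENCODE M21 annotation of GRCm38, the assembly that mm10 denotes, matched on gene ID for 31011 of the 31053 genes.

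A pre-pachytene set and a pachytene set were defined in a random selection of the wild-type cells as genes at least 4-fold higher in wild-type L and Z cells together, or in wild-type eP to MI cells together, than in the other group. The ratio was then taken against the remaining wild-type cells. Genes of the pre-pachytene set needed at least 10 UMIs in the defining L and Z cells. Stage sums were also compared by Spearman correlation across 10372 genes. Each cell labelled Zfp541-/- was in addition given the stage most common among its 15 nearest wild-type cells in 30 principal components of 2000 genes. Wild-type cells left out in turn were given their own stage in 94.38% of cases, within that library only. The earliest spermatogonia, leptotene and preleptotene had 8, 11 and 12 wild-type cells, fewer than the 15 neighbours.

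Doublets were scored per library with Scrublet as implemented in Scanpy 1.11.5. Its automatic threshold called 5 of 12639 wild-type barcodes and 912 of 11580 barcodes labelled Zfp541-/-, so the caller did not work in the wild-type library. No cell was left out for this in the reported values, and leaving out the 6% of barcodes with the highest score in each library was added as an alternative after the data were seen. To compare shares of cells with a UMI across depths, each cell was thinned to 3239 UMIs, which left out 225 wild-type cells and 1497 cells labelled Zfp541-/-. The other alternatives were the scaling, the CPM minimum, mitochondrial and ribosomal protein genes out of the total, equal weight per cell, a 5% mitochondrial limit, a minimum depth, stages from the nearest wild-type cells, the mean of list members and other definitions of the stage sets. Ratios of levels averaged over a stage's clusters and all barcodes in place of annotated cells were added after the data were seen. So were thinned stage sums and lists over mP and lP alone.

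The procedure was tested on simulated independent Poisson counts with the totals of the real stages, which leave out variation between cells and libraries. The changed genes were drawn from those of at least 50 CPM in the wild-type library. All 100 genes changed 2-fold and all 100 changed 4-fold had an interval on the correct side of 0 in eP, mP and lP. Intervals held the true ratio for 95.84% of 7133 genes in eP, 95.37% of 6854 genes in mP and 95.21% of 6700 genes in lP. Of 200 unchanged lists, 2% in eP, 4% in mP and 3.5% in lP fell outside the central 95% of random lists. Python 3.11.15 was used with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and Matplotlib 3.10.9.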

Results

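Single-cell transcriptomes of sorted testicular germ cells were compared between 1 wild-type library and 1 library labelled Zfp541-/-, whose cells are called knockout-labelled in what follows. The wild-type library held 8420 annotated cells with 108612781 UMIs, and the library labelled Zfp541-/- held 8833 annotated cells with 119675250 UMIs. The median annotated cell had 11246 UMIs and 3190 genes in the wild-type library and 10905 UMIs and 3607 genes in the library labelled Zfp541-/-. Each genotype had 1 library and no replicates, so the differences below have no replicate check. The intervals cover counting error only, except where an interval over genes is named. Cells of the same stage name were deeper in the library labelled Zfp541-/-, with median UMIs 2.35 times higher in mid pachytene (18665 against 7945) and 2.57 times higher in late pachytene (23690 against 9210).

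Zfp541 itself was measured first, as a check of the labels. ZFP541 is a zinc finger protein that binds histone deacetylases in spermatocytes. Its gene, ENSMUSG00000078796, lies on chromosome 7 from 16061814 to 16096334 in GRCm38. In mid and late pachytene its level was higher, not lower, in the library labelled Zfp541-/-. In mid pachytene the level was 28.1 CPM (24.9 to 31.6) in the wild-type library and 81.9 CPM (79.4 to 84.5) in the library labelled Zfp541-/-, and in late pachytene it was 35.8 CPM (31.8 to 40.3) and 70.6 CPM (68.2 to 73.1). Within early pachytene cluster 12 the levels were 43.6 and 60.5 CPM, a log2 ratio whose interval of -0.32 to 1.40 includes 0, and within cluster 16 they were 18.3 and 76.0 CPM. From the last spermatogonial stage to zygotene, where the wild-type library had 1 to 3 Zfp541 UMIs per stage, the wild-type level was the higher, at 21.3 and 11.0 CPM, 39.6 and 27.5 CPM, 81.1 and 44.4 CPM, and 47.6 and 46.2 CPM, with overlapping intervals.

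The share of mid pachytene cells with at least 1 Zfp541 UMI was 19.7% in the wild-type library and 75.1% in the library labelled Zfp541-/-, and 7.27% and 24.8% after thinning to 3239 UMIs. In late pachytene the thinned shares were 9.45% and 20.1%, against 28.8% and 78.1% at full depth. The earliest spermatogonia of the library labelled Zfp541-/-, with a median of 9280.5 UMIs, had a UMI in 7.80% of cells, and 1.89% after thinning. The labels do not say which part of the gene was deleted, and a 3' tag outside that part checks nothing, so these counts leave the genotype label unchecked. Every direction below is therefore drawn between the library labelled Zfp541-/- and the wild-type library as labelled.

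The stages present in each library address how far germ cells of each genotype progress. The wild-type library was mostly diplotene and later, while the library labelled Zfp541-/- had almost no cells past late pachytene. Diplotene and first meiotic division cells made up 54.4% (53.3 to 55.4%) of wild-type cells and 0.147% (0.078 to 0.252%) of knockout-labelled cells, 13 cells that were all annotated as diplotene. Round and elongated spermatids made up 17.3% (16.5 to 18.1%) of wild-type cells and 0 of 8833 knockout-labelled cells, which allows a share of up to 0.034%. Cells from spermatogonia to zygotene made up 1.45% (1.21 to 1.73%) of wild-type cells and 36.3% (35.3 to 37.4%) of knockout-labelled cells. The pachytene stages held 26.9% (25.9 to 27.8%) and 63.5% (62.5 to 64.5%).

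Shares depend on the sort for tetraploid cells and on cell depth. Spermatids are haploid, so those in the wild-type library were outside the gate that the protocol names, and the sort settings of each library are not given in the sources used here. Knockout-labelled cells from spermatogonia to zygotene had median UMIs from 2276 in leptotene to 9280.5 in the earliest spermatogonia. With cells above 5% mitochondrial UMIs left out, their share was 17.1%, and with the shallowest cells left out it was 23.9%. The wild-type share of these stages was 1.12% and 0.342% under the same settings. With every barcode of at least 1000 genes and at most 10% mitochondrial UMIs, spermatids made up 31.0% of the wild-type library. Sizes of single clusters are not compared, because clusters 10, 13, 15, 17, 18 and 21 were almost entirely knockout-labelled cells and clusters 3, 6, 8, 14, 19, 20, 23 and 24 held wild-type cells only.

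**Figure D1:**
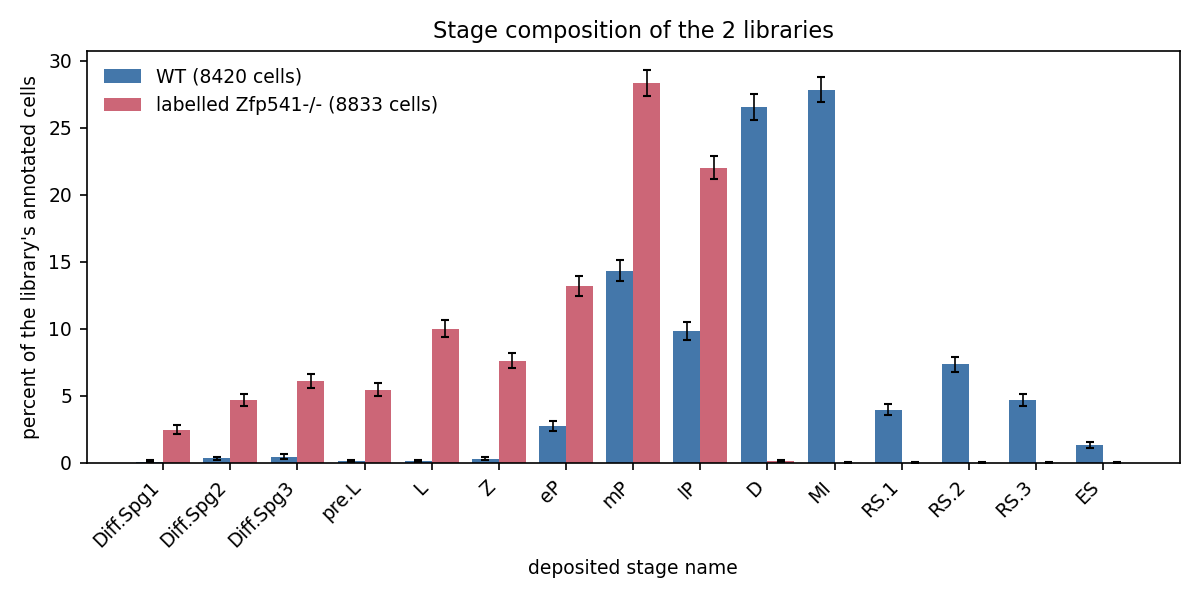
Percent of each library's annotated cells (vertical axis) in each deposited stage (horizontal axis), wild-type in blue and the library labelled Zfp541-/- in red, with exact 95% intervals for counting error. From diplotene on, the library labelled Zfp541-/- has 13 of 8833 cells, whereas the wild-type library has 71.7% of its cells there.

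Gene expression was then compared within mid and late pachytene, the stages in which chromosomes are fully paired and crossovers mature. The genes with the largest differences in late pachytene were nearly absent from the cells of one library and present in those of the other. Prps1l1, a testis-specific phosphoribosyl pyrophosphate synthetase on chromosome 12 (34984761 to 34986436), was at 668.5 CPM in wild-type and 4.40 CPM in knockout-labelled late pachytene cells, a log2 ratio of -7.25 (-7.46 to -7.05). Bend6, a BEN domain transcriptional corepressor on chromosome 1 (33852052 to 33907816), had 0 UMIs in wild-type and 7371 UMIs in knockout-labelled late pachytene cells, at least 418-fold higher. Across 7635 genes measured in late pachytene, the central 90% of log2 ratios spanned 5.78. In mid pachytene the span was 4.30 over 7701 genes. These spans hold library differences as well as any genotype difference.

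Among the other genes lower in late pachytene, Pbp2, a phosphatidylethanolamine-binding protein of the testis, was at 421.6 CPM in the wild-type and 3.80 CPM in the library labelled Zfp541-/-. Timm8a2, a relative of a mitochondrial import chaperone, was at 84.9 and 0.38 CPM. Pudp, a pseudouridine phosphatase, was at 70.9 and 0.36 CPM, and Wdr20rt, a retrogene, at 72.6 and 0.17 CPM. The testis transcripts 1700003I22Rik, 1700016K05Rik and 1700047M11Rik were at 179.7, 188.4 and 67.3 CPM in the wild-type library and at 0.17, 1.30 and 0.15 CPM in the library labelled Zfp541-/-. In mid pachytene, Slco6c1, a gonadal organic anion transporter, was at 186.3 and 3.22 CPM and Nlrp14, a germline member of the NLR family, at 146.2 and 2.93 CPM. The transcript 1700026J12Rik, named by the mean over stages, was at 192.4 and 3.26 CPM in late pachytene.

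The protamine transcripts Prm1 and Prm2, which package sperm chromatin, were also among the lowest. Prm1 had 724 UMIs in wild-type and 0 in knockout-labelled late pachytene cells, at least 1418-fold lower. Tnp1, which encodes a transition protein, had 191 and 0 UMIs, at least 374-fold lower. Prm2 had 501 UMIs and 1 UMI, a log2 ratio of -10.94 (-16.83 to -9.04). Wild-type cells from spermatogonia to zygotene, which should lack these transcripts, carried 1.63 UMIs of the elongating spermatid markers per cell, and wild-type mid pachytene cells 2.51 UMIs.

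Genes higher in the knockout-labelled late pachytene cells had many kinds of product. They included the neuronal intermediate filament Ina (0.13 and 135.5 CPM in the wild-type and knockout-labelled libraries), the retinaldehyde reductase Dhrs3 (0.88 and 224.4 CPM) and the secreted growth factor binding protein Igfbp7 (1.25 and 244.7 CPM). The maternally expressed imprinted RNA Meg3 was at 0.13 and 75.4 CPM, Fam26f at 0.13 and 77.0 CPM, and Tmem160 at 0.75 and 218.9 CPM. Rcan3, a regulator of calcineurin, had 0 wild-type UMIs and was at least 209-fold higher. Ddah1, an enzyme that degrades methylarginines, was at least 188-fold higher, and the transcript 3010003L21Rik at least 418-fold higher. In mid pachytene the thioesterase Acot13 was at 1.54 and 254.3 CPM, the scaffold protein Iqgap2 at 0.21 and 85.6 CPM, Fam81a at 0.41 and 101.8 CPM, and the corepressor Irf2bp2 at 0.21 and 66.1 CPM. The fatty acid desaturase Fads1 was at 0.63 and 91.5 CPM in late pachytene.

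Of these genes, Ina, Dhrs3, Fam26f, Bend6, Igfbp7, Meg3, Acot13, Tmem160, Iqgap2 and Fads1 also rank among the 10 leading genes of mid or late pachytene clusters, ranked by fold. Late pachytene held clusters 0, 5 and 22, with 486, 107 and 234 wild-type cells and 959, 884 and 102 knockout-labelled cells. With each library's levels averaged over these clusters at equal weight, the late pachytene log2 ratios were 9.78 for Ina, 8.09 for Dhrs3 and 7.60 for Tmem160. In the whole stage they were 9.49, 7.90 and 8.07. In cells thinned to the same UMIs, the late pachytene log2 ratio was 7.04 for Tmem160, -7.93 for 1700003I22Rik (from -9.95) and -5.99 for Pudp (from -7.57).

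**Figure D2:**
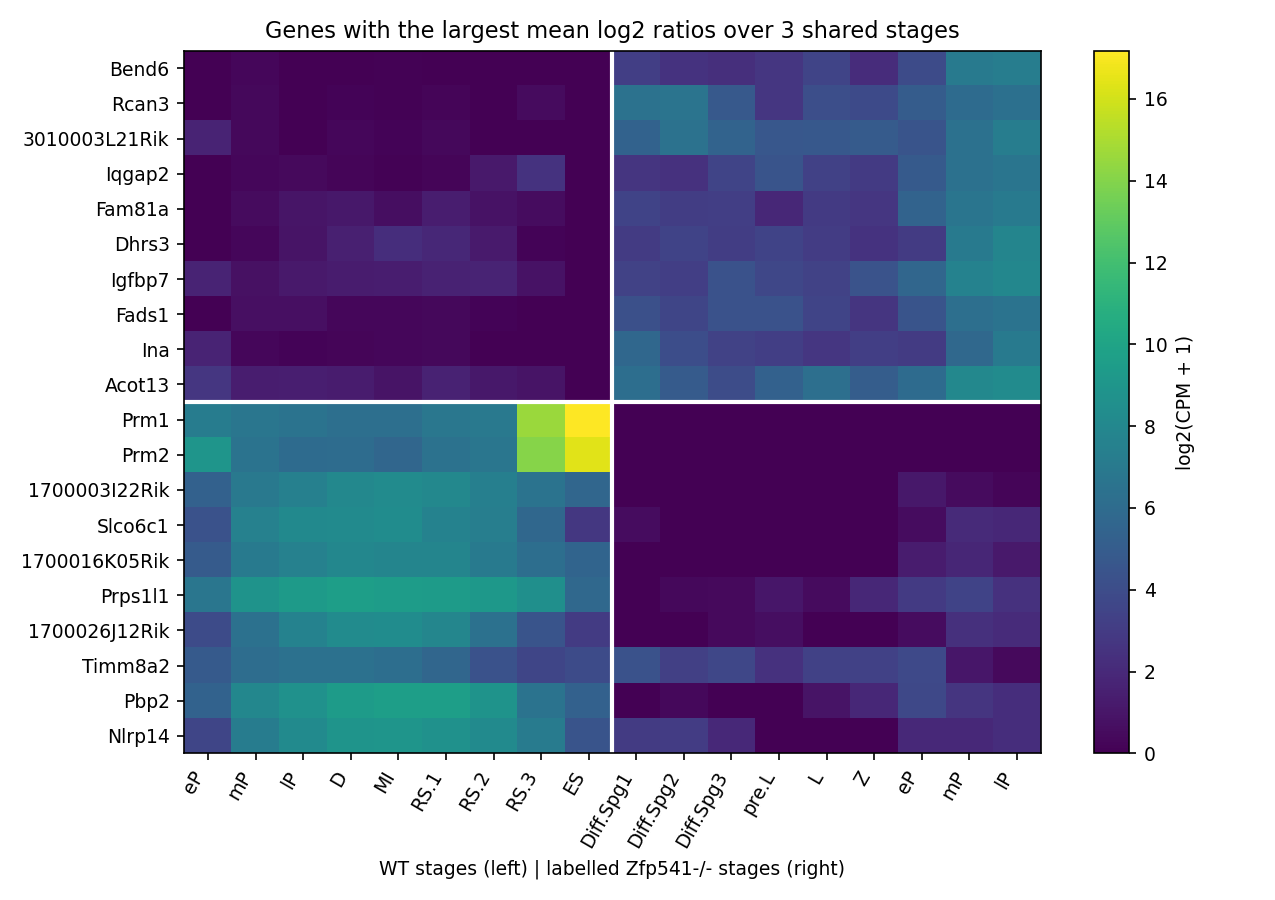
Level of 20 genes, as log2(CPM + 1) in colour, in the stages of the wild-type library (left) and of the library labelled Zfp541-/- (right) with at least 50 cells. The genes are the 10 with the highest and the 10 with the lowest mean log2 ratio over 3 shared stages, among genes with a mean of at least 50 CPM in the higher library and without mitochondrially encoded, ribosomal protein and Y-linked genes. Bend6 is at 0 CPM in wild-type and 157.3 CPM in knockout-labelled late pachytene, and Prps1l1 at 668.5 and 4.40 CPM.

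Early pachytene was compared within its clusters, although means over the 3 shared stages include it as annotated. Cluster 12 held 75 wild-type and 713 knockout-labelled cells, and cluster 16 held 155 and 451. Ptma, which encodes the abundant nuclear protein prothymosin alpha, was at 103.9 and 1005 CPM in cluster 12 and at 83.2 and 1026 CPM in cluster 16. The plasma membrane calcium pump Atp2b1 had 2 wild-type UMIs in each cluster, with log2 ratios of 3.98 (2.44 to 7.35) in cluster 12 and 4.86 (3.32 to 8.23) in cluster 16. Tropomyosin Tpm1 was at 13.4 and 151.3 CPM in cluster 12, the imprinted adaptor Grb10 at 10.1 and 91.4 CPM, and the ferritin light chain Ftl1 at 10.1 and 105.9 CPM. Asparagine synthetase Asns and the homeobox gene Pbx3 had 1 wild-type UMI each in cluster 12, with log2 ratios of 3.48 (1.58 to 9.38) and 3.63 (1.72 to 9.52). The histone methyltransferase gene Kmt2a was at 16.8 and 118.0 CPM there, and Rasgrp2, an activator of Rap GTPases, at 0 and 87.1 CPM.

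Lower in both early pachytene clusters were Prps1l1 (63.7 and 4.75 CPM in cluster 12), the antisense transcript Kdm6bos (67.0 and 6.19 CPM), Myl10, a myosin light chain gene (201.1 and 17.8 CPM), and Dbil5, a relative of acyl-CoA binding protein (77.1 and 16.7 CPM). Gm48544 was at 43.6 and 12.6 CPM, the POU factor Pou2f2 at 36.9 and 8.46 CPM, and Gm15517 had 23 wild-type UMIs and 1 knockout-labelled UMI there, a log2 ratio of -7.99 (-13.91 to -5.92). Tnp2, which encodes a transition protein, had 22 and 0 UMIs in cluster 12 and 34 and 0 in cluster 16. Gm48544 and Pou2f2 were also among the 10 leading genes of diplotene cluster 1, which held 656 wild-type and 11 knockout-labelled cells. Whether RNA released by later wild-type cells gave the wild-type counts of these early pachytene genes was not tested.

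The gene lists fixed beforehand describe which processes these differences touch. In mid pachytene the medians of the recombination, synapsis and premeiotic replication lists were above the central 95% of random lists, and those of sperm energy metabolism and the flagellum were below it. In late pachytene the synapsis list was inside it. The 24 measured genes of double-strand break formation and recombination had a median log2 ratio of 0.72 in mid pachytene, with 18 above 0 and 9 at least 2-fold higher, above 99.97% of random lists. In late pachytene the median was 0.81, with 16 of 20 above 0. The summed level of the whole list is set by its most abundant members. In mid pachytene it was 3791 CPM in the wild-type and 3762 CPM in the knockout-labelled library, and in late pachytene 2927 and 3277 CPM. In early pachytene as annotated, whose clusters are mixed differently in the libraries, it was lower, at 6861 and 5971 CPM. Within clusters 12 and 16 the list's median log2 ratio was 0.20 and 0.26. Over the 3 shared stages the list's median was 0.59. It was 0.48 among genes of at least 50 CPM (96.2%) and 0.43 with cells named from their nearest wild-type cells (97.4%). Both lay inside the central 95% of random lists. Tex15, needed for loading recombinases on breaks, was at 1.25 CPM in wild-type and 45.2 CPM in knockout-labelled late pachytene cells, and Mei1, needed for break formation, at 1.00 and 39.1 CPM. Gm960, which encodes the partner of SPO11, was at 2.63 and 11.5 CPM, and the recombinase gene Dmc1 at 0.63 and 1.62 CPM.

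Synaptonemal complex and meiotic cohesin genes had medians of 0.54 in mid pachytene (99.1% of random lists lower) and 0.49 in late pachytene (96.1%), with members on both sides of 0. The cohesin gene Smc1b, on chromosome 15 (85064689 to 85131964), was at 259.3 CPM in wild-type and 1377 CPM in knockout-labelled late pachytene cells, a log2 ratio of 2.41 (2.35 to 2.47). The central element gene Syce3 was at 287.8 and 927.4 CPM and 4930447C04Rik, another central element gene, at 32.5 and 120.0 CPM, whereas the central element gene Syce2 was lower, at 94.1 and 15.4 CPM. Over the 3 shared stages this list's median was 0.50, and 0.27 (95.2%) under the same naming from nearest cells or 0.45 (96.6%) as the mean of members, both inside the central 95% of random lists.

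Premeiotic S phase and meiotic entry genes had medians of 0.85 in mid pachytene (8 of 11 above 0, 98.7% of random lists lower) and 0.94 in late pachytene (7 of 10, 98.5%). Hells, a chromatin remodeller of replicating cells, was at 24.2 and 153.8 CPM in late pachytene. Gm4969, which encodes the meiotic initiator MEIOSIN, was at 0.10 and 14.0 CPM in mid pachytene, the replicative helicase gene Mcm2 at 0.00 and 3.50 CPM, and Mcm4 at 1.13 and 5.33 CPM. The early gene Stra8, chosen outside the naming rule, was at 0.00 and 1.22 CPM in late pachytene. Its UMIs per knockout-labelled cell were 0.0473 in early pachytene as annotated, 0.0456 in mid and 0.0293 in late pachytene. The late pachytene value was 0.0152 of that per knockout-labelled cell before pachytene. Whether RNA released by those earlier cells gave counts this low was not tested. The library labelled Zfp541-/- had 36.3% of its cells before pachytene. Preleptotene markers, which share genes with this list, had medians of 0.85 and 0.41 in mid and late pachytene and a mean of 0.79 over the 3 stages (95.7% of random lists lower), or 0.88 (97.6%) after thinning, with Mcm5 at 4.39 and 9.54 CPM and Mcm6 at 11.0 and 22.5 CPM in late pachytene. Leptotene-zygotene markers had medians of 0.40 and 0.42 and a mean of 0.44 (97.1%), or 0.47 (98.0%) after thinning, with Meiob, a recombination protein, at 15.0 and 29.7 CPM.

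The ZFP541 complex list had medians of 0.82 in mid pachytene (97.7% of random lists lower) and 0.77 in late pachytene (94.6%), with 4 of 5 and 3 of 5 members above 0, Zfp541 included. The mean of its members in place of the median gave 0.59 over the 3 shared stages (88.2%), from 0.81, and mid and late pachytene alone gave 0.79 (96.6%), both inside the central 95% of random lists. Hdac1, a histone deacetylase, was at 99.8 and 230.4 CPM in late pachytene, and Kctd19, a partner of ZFP541, at 131.6 and 224.6 CPM. Hdac2 was at 21.2 and 17.3 CPM, a log2 ratio of -0.30 (-0.53 to -0.05), and Dnttip1 at 116.7 and 113.6 CPM, with an interval of -0.14 to 0.06. Elmsan1 had 0 wild-type UMIs and 4.50 CPM in the library labelled Zfp541-/-, below the level set for list members.

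Testis energy metabolism genes had medians of -0.62 in mid pachytene, with 11 of 13 members below 0 (0.435% of random lists lower), and -0.41 in late pachytene, with 12 of 13 below 0 (2.48%). The glycolytic enzyme genes Pgam2, Pgk2 and Eno4 were at 1457, 35.1 and 26.2 CPM in wild-type and at 290.8, 6.06 and 5.91 CPM in knockout-labelled late pachytene cells, and hexokinase Hk1 at 25.4 and 0.45 CPM. Flagellum and axoneme genes had medians of -0.42 and -0.40, with 17 of 24 members below 0 in each stage (0.24% and 0.48% of random lists lower). The tektin genes Tekt2, Tekt3 and Tekt5 were at 122.8, 67.8 and 16.3 CPM in wild-type and at 18.6, 2.65 and 0.73 CPM in knockout-labelled late pachytene cells, while the dynein gene Dnaic2 was higher, at 5.39 and 41.0 CPM. Limited to genes of at least 50 CPM, the mean over 3 stages was -0.48 for energy metabolism, from -0.66, and -0.27 for the flagellum, from -0.41, both within the central 95% of random lists.

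Markers of later meiosis were low together with these lists. Diplotene and meiotic division markers had medians of -0.45 and -0.39 in mid and late pachytene and a mean of -0.41 over the 3 stages (1.97% of random lists lower). That mean was -0.38 (3.53%) in cells thinned to the same UMIs, -0.38 (3.26%) with cells named from their nearest wild-type cells, -0.32 (7.45%) over mid and late pachytene alone and -0.14 (20.2%) among genes of at least 50 CPM, each inside the central 95%. Pou5f2, a POU factor of late spermatocytes, was at 122.0 and 5.23 CPM in late pachytene, the meiotic kinase Aurkc at 34.6 and 1.58 CPM and the meiotic cyclin Ccna1 at 24.6 and 6.14 CPM, while the kinetochore motor gene Cenpe was at 20.4 and 37.9 CPM. The wider G2/M and meiotic division list had a mean of -0.03 (21.9%), with securin Pttg1 at 403.3 and 110.6 CPM and the mitotic cyclin Ccna2 at 0.13 and 12.4 CPM. Pachytene markers had medians of -0.31 and -0.27 and a mean of -0.31 (5.92%). That mean was -0.41 (2.21%) after thinning and -0.54 (1.29%) as the mean of members, both outside the central 95%. The relaxin-family gene Insl6 was at 368.0 and 109.8 CPM and Adam3, a sperm surface protein, at 225.7 and 210.7 CPM. Elongating spermatid markers, found also in wild-type cells before pachytene, had medians of -12.07 and -11.14, or -9.49 and -9.13 with members at 0 UMIs set to their bound, below all random lists.

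With the settings chosen beforehand, the lists for the remaining processes lay inside the central 95% of random lists over the 3 stages. Acrosome genes had a mean of -0.35 (6.52% of random lists lower), or -2.70 with no CPM minimum, with Acrbp at 524.4 and 121.1 CPM, acrosin Acr at 80.5 and 61.0 CPM and Zpbp at 219.1 and 165.3 CPM in late pachytene. Testis histones had a mean of -0.34 (11.3%), or -0.62 (1.62%) with cells named from their nearest wild-type cells, with the linker histone Hist1h1t at 104.9 and 23.3 CPM, H2afx at 233.7 and 176.8 CPM, H3f3b at 3067 and 2367 CPM, and Hist1h2ba at 33.5 and 30.5 CPM. Sex chromosome silencing factors had a mean of 0.43 (93.3%), or 0.52 (97.7%) with no CPM minimum, with Atrip, the partner of the kinase ATR, at 18.2 and 55.4 CPM, its activator Etaa1 at 8.15 and 20.0 CPM, Setdb1 at 41.1 and 74.5 CPM and the checkpoint gene Hus1 at 6.14 and 9.62 CPM. The piRNA pathway had a mean of 0.19 (80.3%), with Mael at 677.8 and 1093 CPM, Mov10l1 at 86.4 and 139.0 CPM, Tdrkh at 82.8 and 124.1 CPM and Gtsf1 at 774.8 and 400.2 CPM. Transcription regulators of pachytene and spermatids had a mean of 0.01 (47.6%), with Brdt at 163.3 and 245.2 CPM and Tcfl5 at 480.3 and 236.9 CPM. p53 targets and apoptosis genes had a mean of 0.47 (73.8%), with Trp53inp1 at 7.27 and 31.8 CPM, Trp53 at 7.27 and 18.2 CPM and Bax at 11.5 and 28.1 CPM. Pmaip1, which encodes the proapoptotic protein NOXA, was lower, at 2.98 and 0.92 CPM in mid pachytene.

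Mitochondrially encoded transcripts were higher in knockout-labelled cells, with medians of 1.26 in mid and 1.11 in late pachytene and all 12 measured genes above 0 in mid pachytene, above all 10000 random lists. mt-Nd2 was at 125.3 and 644.3 CPM in late pachytene, mt-Nd1 at 222.8 and 697.4 CPM, mt-Nd3 at 43.0 and 128.8 CPM and mt-Atp6 at 2361 and 6490 CPM, and the median mitochondrial percent of a late pachytene cell was 1.26 in the wild-type and 2.22 in the library labelled Zfp541-/-. Ribosomal protein genes had medians of 0.25 and 0.24 (99.99% and 99.93% of random lists lower), with Rps12 at 528.3 and 1057 CPM, Rps21 at 473.6 and 983.1 CPM and Rpl13a at 16.7 and 38.3 CPM.

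Lists with fewer than 5 measured members are given as summed levels in late pachytene. Spermatogonium markers were at 573.1 CPM in the wild-type library and 485.6 CPM in the library labelled Zfp541-/-, nearly all from Dmrtb1 (563.9 and 440.3 CPM), a transcription factor of meiotic entry, with Sohlh2 at 0.25 and 1.43 CPM and Uchl1 at 7.14 and 24.1 CPM. Round spermatid markers were at 25.8 and 1.20 CPM, with the acrosomal gene Spaca1 at 2.13 and 0.49 CPM. Wild-type zygotene and late pachytene cells alike carried 0.250 and 0.249 UMIs of the round spermatid markers per cell. Immediate early and heat shock genes were at 317.8 and 328.3 CPM, with the chaperones Dnajb1 at 275.9 and 293.3 CPM and Hsph1 at 29.6 and 26.4 CPM. Of other testis cells, Sertoli markers were at 6.39 and 12.3 CPM (the protease gene Ctsl at 4.89 and 10.1 CPM), Leydig markers at 5.26 and 3.05 CPM, peritubular myoid markers at 4.64 and 0.832 CPM and macrophage markers at 2.88 and 2.28 CPM. Endothelial markers were at 1.25 and 0.491 CPM and red cell markers at 0.125 and 0 CPM.

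Within the early pachytene clusters, premeiotic S phase genes had medians of 0.92 in cluster 12 and 0.95 in cluster 16 (100% and 99.7% of random lists lower), and energy metabolism genes -0.52 and -0.86 (2.16% and 0.02%). Recombination genes, at 0.20 and 0.26 (81.5% and 55.0%), lay nearer to random lists there. p53 targets had medians of -0.53 in cluster 12 and 0.39 in cluster 16 (1.12% and 53.3%). Synaptonemal complex genes were at 0.22 and 0.40 (95.3% and 97.8%), the ZFP541 complex at 0.42 and 1.03 (89.5% and 98.8%), and the flagellum list at -0.24 and -0.21 (8.55% and 2.39%). Mitochondrially encoded genes were at 1.08 and 1.10, above all random lists. The X-linked list was measured in cluster 12, at 0.99 (91.0%).

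**Figure D3:**
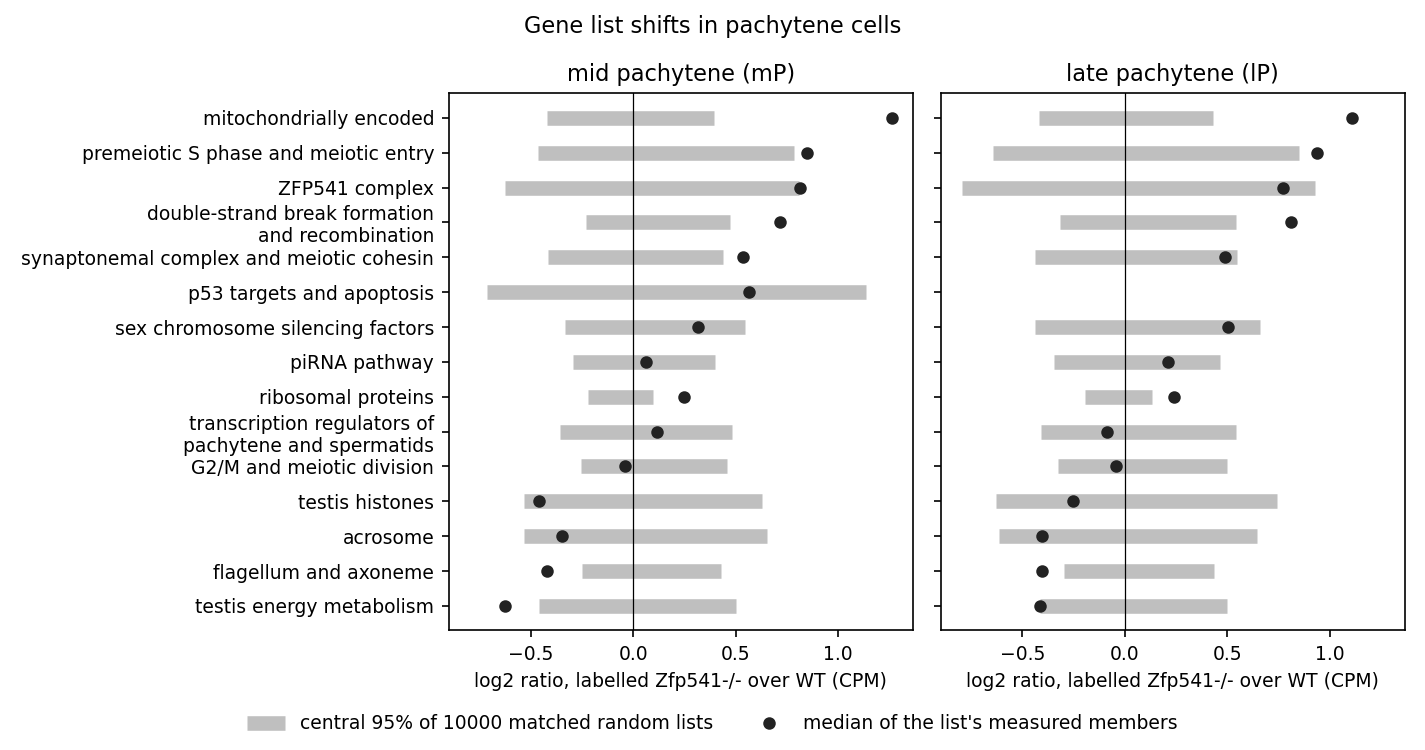
Median log2 ratio of the library labelled Zfp541-/- to the wild-type library (horizontal axis, points) for each fixed gene list in mid and late pachytene. Grey bars span the central 95% of 10000 random lists matched on expression. The recombination list is at 0.72 and 0.81, right of its bar, and the flagellum list at -0.42 and -0.40, left of it.

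The wild-type cells themselves gave a second view of stage identity, through genes that distinguish leptotene and zygotene from later meiosis. The 243 genes of the pre-pachytene set were slightly higher in knockout-labelled cells, with medians of 0.19 in mid pachytene (139 of 234 above 0, 99.2% of random lists lower) and 0.38 in late pachytene (147 of 227, above all 10000 random lists). The 718 genes of the pachytene set were lower, with medians of -0.42 in mid pachytene (489 of 691 below 0) and -0.53 in late pachytene (517 of 708), below all 10000 random lists in each. This set was defined on eP to MI cells together, and the wild-type library held 4578 diplotene and MI cells and 2264 pachytene cells. The set can therefore mark stages after pachytene as well as pachytene itself. With the sets defined at 2-fold, the mid pachytene median of the pre-pachytene set was 0.06, inside the central 95% of random lists. The wild-type L and Z cells that defined the sets held 45954 UMIs in all, so weakly expressed genes were not detectable as members at this depth.

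Profiles of whole stages were then matched, to ask which wild-type stage each knockout-labelled stage resembles. Knockout-labelled mid pachytene correlated best with wild-type mid pachytene (Spearman 0.925 across genes, which are not independent replicates). Knockout-labelled late pachytene correlated better with wild-type mid pachytene (0.914) than with wild-type late pachytene (0.897). Of 1945 single knockout-labelled late pachytene cells, 1794 (92.2%) were nearest to wild-type mid pachytene cells and 151 to wild-type late pachytene cells. The 13 knockout-labelled diplotene cells were nearest to wild-type late (9) or mid pachytene cells (4). On the authors' pseudotime score, the median knockout-labelled late pachytene cell was at -13096 and the median wild-type cell at -11784, a difference of -1312, while in mid pachytene the difference was 186.

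X and Y genes are silenced in pachytene spermatocytes, and both libraries had a low share of X UMIs there, with a higher share in the library labelled Zfp541-/-. X genes held 2.68% of UMIs in wild-type and 2.65% in knockout-labelled leptotene cells. In mid pachytene the shares were 0.0182% (0.0174 to 0.0191%) and 0.0357% (0.0352 to 0.0363%), and in late pachytene 0.0131% (0.0123 to 0.0139%) and 0.0368% (0.0363 to 0.0374%). Wild-type round spermatids of the last stage, after meiosis, were at 1.30%. Y genes held 0.00034% and 0.00359% of UMIs in late pachytene and 0.00055% and 0.00179% in mid pachytene. In early pachytene as annotated, not split by cluster, they held 0.00445% and 0.00331%, and the intervals overlap (0.00318 to 0.00606% and 0.00294 to 0.00372%).

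Of the X-linked list, Rpl39, a ribosomal protein gene, was the only member with a mean level high enough to be measured over the 3 shared stages, and it was at 1.00 and 7.40 CPM in late pachytene. Among X and Y genes chosen after their values were seen, the late pachytene UMIs in the wild-type and knockout-labelled libraries were 1 and 573 for Ubl4a, 0 and 312 for Cetn2, which encodes a centrin, 0 and 285 for Fmr1, and 6 and 1188 for the Y gene Gm47283. Ndufa1, a subunit of respiratory complex I, went the other way, at 37.0 and 17.7 CPM. The summed level of the X-linked list was 4.51 and 49.0 CPM in late pachytene, and that of the Y-linked list 0.877 and 10.5 CPM. In early pachytene as annotated, not split by cluster, the Y-linked list was at 35.6 and 20.0 CPM.

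**Figure D4:**
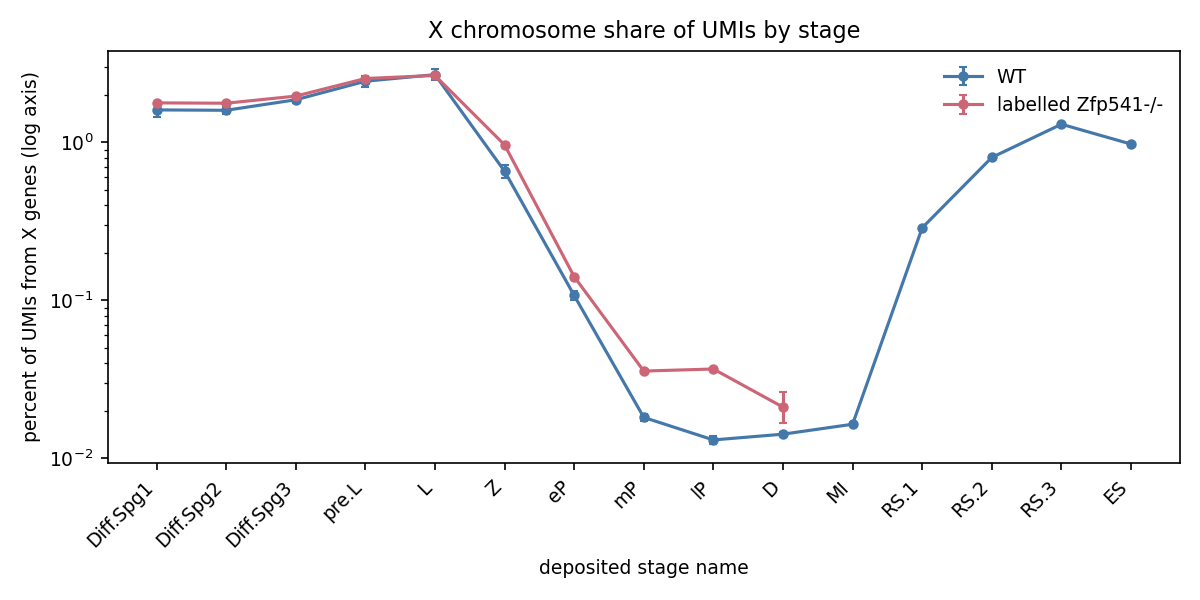
Percent of UMIs from X genes (vertical log axis) by deposited stage (horizontal axis) in the wild-type library (blue) and the library labelled Zfp541-/- (red), with exact 95% intervals for counting error. Both libraries are near 2.7% in leptotene and under 0.04% in late pachytene, where the library labelled Zfp541-/- is at 0.0368% and the wild-type library at 0.0131%.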

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

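The tests on elongating spermatid transcripts, on less advanced cells for the lower genes, on free RNA for the higher genes, on the choice of barcodes and on the sort gate were chosen after the result was seen. Hdac2 and Syce3 had ratios of opposite sign in different stages. For Hdac2 the log2 ratio of the library labelled Zfp541-/- to the wild-type library was 1.065 in early, 0.193 in mid and -0.297 in late pachytene. For Syce3 it was -0.366, 1.101 and 1.688. The difference between stages was not tested, and early pachytene is a class whose 2 clusters are mixed differently in the libraries.

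A signal also lay in barcodes outside the authors' annotation. Of these, 3492 wild-type barcodes and 440 barcodes labelled Zfp541-/- had at least 1000 genes and at most 10% mitochondrial UMIs. The wild-type barcodes had a median of 4693.5 UMIs and were nearest mostly to spermatids, 967 to the first and 862 to the second round stage. The barcodes labelled Zfp541-/- had a median of 16580.5 UMIs, and 330 were nearest to mid pachytene. Also outside the annotation, 91 wild-type barcodes and 2013 barcodes labelled Zfp541-/- had over 10% mitochondrial UMIs.

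The first pattern is the set of genes at least 4-fold lower in late pachytene cells labelled Zfp541-/-. Apart from the elongating spermatid markers, this set and the set of higher genes hold only genes of at least 50 CPM in the higher library. Mitochondrially encoded, ribosomal protein and Y-linked genes are left out. For elongating spermatid transcripts, free RNA from spermatids may be the source of the difference, since wild-type cells before pachytene carried 0.65 (0.561 to 0.751) of the UMIs of a mid pachytene cell. For the other lower genes the ratio was taken to late pachytene cells. Its median over genes was 0.0321, the ratio of summed UMIs was 0.0794, and 6.54% of the genes reached the limit set for free RNA. These values argue against free RNA as the whole cause for most of these genes. Less advanced cells stay open as a cause for these genes, although 64.05% lay at least 2-fold below every wild-type pachytene level. Those reference levels may themselves hold free RNA, which was not subtracted. Wild-type cells before pachytene carried 20.09 summed UMIs of these genes per cell, against 253.133 per late pachytene cell. The median gene lay at log2 -1.573 to the lowest wild-type pachytene level, with quartiles of -2.681 and -0.386. Its interval of -2.054 to -1.278 is a 95% order-statistic interval over genes, which counts genes as independent. The genes were chosen on the same late pachytene counts, which favours low values. The genotype and the single library of each genotype cannot be told apart as sources, because the design holds 1 library of each.

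The second pattern is the set of genes at least 4-fold higher. Free RNA from cells before pachytene is argued against for most of them. The median gene had 3.942 times as many UMIs per late pachytene cell as in its highest earlier stage, and 96.92% had a ratio over 0.5. Hells was under that, at 0.478, and Ftl1, at 0.155, was under the limit set for free RNA. These genes were chosen on high late pachytene counts, which favours high ratios. Whether the cells are less advanced stays open at a median log2 of -0.02 to the highest reference level. That value met the limit of 0 written beforehand for this cause, but the genes lay on both sides, with quartiles of -1.069 and 1.353, and Dhrs3 was 4.446 above every reference. For X genes the ratio of 0.367 also met the limit of 2 written beforehand for free RNA. X genes had nearly flat ratios of 0.0448, 0.0579 and 0.0603 in early, mid and late pachytene, as free RNA would give. Free RNA was left open for them because the autosomal comparison genes were not flat (0.4161, 0.2184 and 0.1643). Ubl4a, chosen after its values were seen, also went from 0.0137 to 0.2946 UMIs per cell. Among autosomal spermatogonium markers, the late pachytene ratio was below the X value for Ccnd2 (0.0203), Dmrt1 (0.021), Sohlh1 (0.0217) and Crabp1 (0.0316). It was above the X value for Uchl1 (0.2514) and Kit (0.4177).

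The third pattern is the absence of cells at diplotene or later beyond 13. The authors' choice of barcodes stays open. Of 2747 barcodes outside the annotation, 0.0% were nearest to such wild-type cells (0 counts allow up to 0.109%), under the limit set for excluding it. Only 440 of them had at least 1000 genes and at most 10% mitochondrial UMIs, so that bound rests mostly on barcodes of low quality. The naming also placed all 13 annotated diplotene cells in late (9) or mid pachytene (4), so it could not have found more. All barcodes labelled Zfp541-/-, in or outside the annotation, held 51 protamine and transition protein UMIs, and the wild-type barcodes 1495923. This measure replaced the whole elongating list after its first value was seen. It leaves little room for last-stage round or elongated spermatids with wild-type levels of these transcripts. Wild-type cells of the first and second round stages held 18.15 and 50.16 UMIs of the elongating list each, against 1495 and 2636 in those later stages. The measure therefore says less about early round spermatids. A sort gate that differed between the libraries stays open, because no DNA content was recorded per cell. An arrest before diplotene in the Zfp541-/- testis is the biological explanation that the design names, and it could not be separated from the gate, the choice of barcodes or the library.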

How the results depend on the processing

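Ratios of levels averaged over a stage's clusters, all barcodes and the 6% highest doublet scores were chosen after seeing the data. So were thinned stage sums and lists over mid and late pachytene alone. No result reversed. Of the list values under all alternatives, 231 kept their side of the central 95% of random lists, 13 moved outside it and 12 moved inside. All 9 nearest-stage results kept their stage. With stages from nearest wild-type cells, which leave 160 late pachytene cells labelled Zfp541-/-, the list means were 0.267 for synaptonemal complex, 0.432 for recombination and -0.621 for histones, and the shares of that library were 34.575% from spermatogonia to zygotene, 65.425% pachytene and 0.0% diplotene and MI. Among genes of at least 50 CPM, which leave fewer members, recombination was 0.476, flagellum -0.271 and energy metabolism -0.481. With no CPM minimum, silencing factors were 0.524, acrosome -2.697, and the widths of the ratios 5.866 in early and 7.383 in mid pachytene, as low-count genes enter. The mean of members gave 0.592 for the complex and 0.451 for synaptonemal complex, and mid and late pachytene alone gave 0.793 for the complex, each inside the central 95%. The mean of members also gave 0.972 for leptotene-zygotene and -0.537 for pachytene markers, both outside it. The 2-fold definition gave 0.062 for the pre-pachytene set in mid pachytene. Thinning gave log2 1.90 and 1.182 for Zfp541 in mid and late pachytene. It put the preleptotene (0.882), leptotene-zygotene (0.469) and pachytene markers (-0.407) outside the central 95% and the diplotene markers (-0.376) inside it. It also moved 9 named gene ratios beyond their counting intervals. Naming from nearest wild-type cells moved 10, such as Wdr20rt in late pachytene from -8.646 to -7.641. For the shares, all barcodes gave wild-type 19.745% pachytene, 48.002% diplotene and MI and 31.002% spermatids. Leaving out called doublets gave 37.668% spermatogonia to zygotene and 62.177% pachytene in the library labelled Zfp541-/-, but the caller failed in the wild-type library. Leaving out cells above 5% mitochondrial UMIs gave 17.125% and 82.666% there and 1.121% wild-type spermatogonia to zygotene. Leaving out shallow cells gave 23.869% and 75.954%, and wild-type 0.342% spermatogonia to zygotene and 55.851% diplotene and MI. Without mitochondrial and ribosomal protein genes in the total, X shares in early, mid and late pachytene were 0.1205%, 0.02019% and 0.01437% wild-type and 0.1539%, 0.03813% and 0.04021% labelled Zfp541-/-. Where the setting does not itself remove cells or genes, the cause was not tested. No paired analysis was possible, because the libraries share only replicate number 1. Lists with fewer than 5 measured members under a setting have no value there.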

Other observations

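The set of genes at least 4-fold higher in late pachytene cells labelled Zfp541-/- held genes of at least 50 CPM. Of these, 29.07% were at least 2-fold above every stage before pachytene of that library and every wild-type pachytene stage. After Dhrs3, the highest were Gsc2 (log2 4.31) and 2210011C24Rik (4.13), chosen after their values were seen, then Fam26f (3.93) and Bend6 (3.87). Among the genes of at least 50 CPM that were at least 4-fold lower, without the elongating spermatid markers, 64.05% were at least 2-fold below every wild-type pachytene level.

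Zfp541 continued to be detected in the wild-type library after pachytene, at 35.8 CPM in diplotene, 39.8 CPM in MI and 9.39 CPM in the last round spermatid stage. Tmem160, one of the genes higher in the library labelled Zfp541-/-, lies on chromosome 7 (16452779 to 16455494), near Zfp541.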
